A study of Homo sapiens with 12 samples.

How the data were processed

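Total RNA of OCI-Ly1 and SU-DHL-4 cells, isolated with an RNA column kit, was made into stranded mRNA libraries for DNBSEQ sequencing, per the labels' protocols. Each line had 3 libraries with DMSO and 3 with 1 µM JNJ-64619178, both for 72 h, and the group and number of each library were taken from its labels. The reads were placed on the human genome hg38, per the submitters' processing notes, and the aligner, the quantifier and the gene annotation are not given in the sources used here.

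The authors deposited 1 table per line, with 15913 genes for OCI-Ly1 and 15877 for SU-DHL-4, of which 15158 were in both. Each table holds for each library a read count, per the file headers, whose values are expected counts in the authors' tables, since only 81.7% to 84.6% of them per library are whole numbers, and they are not scaled for depth. Each table also holds TPM computed by the authors, which sum to the same total in every library over the listed genes and are rounded to 2 decimals. The tables list no mitochondrially encoded gene, and genes listed for only 1 line had no value in the other, so the shares of counts above are shares of the listed genes. Because expected counts divide reads between similar transcripts, single values of genes with near-identical copies, pseudogenes or overlapping genes (ribosomal proteins, histones, HLA genes, UTP14C, ANKHD1-EIF4EBP3) are uncertain. Of 16632 gene identifiers 16579 were found in the RefSeq table of GRCh38 patch 14, from which coordinates were taken, and 16341 of them carried the same symbol there.

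Expected counts were rounded to whole numbers. In each line alone, genes were kept by filterByExpr, libraries were scaled by TMM, and JNJ was compared with DMSO by the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest, R 4.3.3), with the Benjamini-Hochberg adjustment at 0.05. The response of the lines was compared by an interaction contrast over all 12 libraries with 1 mean per group. Fitted log2 changes use a prior count of 0.125. Overlaps of calls were tested with a one-sided Fisher's exact test. For 32 gene lists with 736 genes, camera (limma 3.58.1, on voom values) with a preset correlation of 0.01 tested whether the members of lists with at least 4 tested genes moved relative to the other genes, adjusted over the 31 lists tested, with an estimated correlation and with fry beside it. Members were counted over all genes tested and adjusted over the list alone. A list moved when camera's adjusted p with the preset correlation was at most 0.05.

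Named genes followed a fixed rule. For each line these were the 8 highest and 8 lowest log2 changes among called genes with a mean of at least 10 CPM in the higher group and no overlap between the 3 DMSO and 3 JNJ libraries. For each list they were up to 4 called members with the smallest adjusted p over the lines. For both lines together and for the difference between lines they were the 6 highest and 6 lowest. Clone, antisense, non-coding and immunoglobulin segment names were skipped, and 21 genes of PRMT5 and apoptosis biology were always included, for 179 genes in all, of which the text names a part. ALG11 and ANKHD1 are named because they overlap a gene of the rule, and genes named in the closing part on gene families and transcript lengths were chosen after their values were seen.

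The gene tests and list tests of the lines and of their difference, and the length tests of the lines, were tested on simulated values drawn from the means, spread and library sizes of the real libraries, with 67, 67 and 66 genes changed by a log2 value of 0.5, 1 and 2. In the OCI-Ly1 simulation (12584 genes) edgeR recovered 67.2%, 89.6% and 98.5% of them, with 16 false calls among 186. In the SU-DHL-4 simulation (12279 genes) the shares were 71.6%, 88.1% and 98.5%, with 18 false calls among 190. For the difference between lines (12979 genes) they were 47.8%, 85.1% and 93.9%, with 4 false calls among 155. The false shares of the single lines, 8.60% and 9.47%, lie above the nominal 5%. For DESeq2, used as an alternative below, they were 14.6% in OCI-Ly1 and 16.1% in SU-DHL-4, and for limma-voom 8.60% and 8.06%. Of 3 lists with every member shifted by a log2 value of −0.5 in each line, camera recovered 3, with 0 of 28 other lists called. The same numbers held for the difference. Smaller shifts and lists with only some members shifted were not simulated, so recovery of such lists is not known. Simulated genes vary independently, so these runs do not test correlation between genes, and the overlap, the correlation across genes and the matched lists were not simulated. Few simulated genes changed, while 66.0% of OCI-Ly1 and 63.4% of SU-DHL-4 genes were called in the data. The recovered and false shares may therefore not carry over, and scaling with most genes changed was not tested. For changes of transcript length the simulation recovered 81.0% and 97.0% of shifts of 0.1 and 0.3 in OCI-Ly1 and 93.0% and 96.0% in SU-DHL-4, with 3 false calls among 181 and 12 among 201.

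The alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no low-count filter, a stricter filter (at least 1 CPM in at least 3 libraries), limma-voom, the replicate number as a block, all 12 libraries in one fit, each library left out in turn, an adjusted p of 0.01 and an absolute log2 change of at least 1. Scaling by library totals and limma on log2(TPM + 1) were added after the data were seen. In the TPM fit each library was centred at its median over the genes tested, so its changes are relative to that median. Totals per library of 51950281 to 55608535 counts set the counting error, and precision between groups is set by n = 3. Intervals for counting alone were not needed because every comparison has replicates, and a group at 0 counts was given a floor of 3 counts per library. Replicate libraries differed by more than sampling noise (chi-square per gene 3.29 to 52.9), so none was counted as a repeat of another. Some genes and 1 gene list are not reported here. Genes of sex chromosomes that would tell the sex of a donor were left out of the named genes.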

Results

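OCI-Ly1 and SU-DHL-4 are established human cell lines from diffuse large B-cell lymphoma, a cancer of mature B cells. Each line was kept for 72 h with the solvent DMSO or with 1 µM JNJ-64619178 (JNJ below), an inhibitor of PRMT5, the enzyme that makes most symmetric dimethylarginine in the cell and that modifies Sm proteins of the spliceosome. The series asks how blocking PRMT5 alters these cells in a study of their sensitivity to apoptosis started from inside the cell or through death receptors. Messenger RNA was sequenced in 3 libraries per group, 12 in all. The authors' expected counts summed per library to between 53429661 and 54257561 in OCI-Ly1 with DMSO and to between 52434436 and 54663262 with JNJ. In SU-DHL-4 the totals lay between 54183600 and 55608535 with DMSO and between 51950281 and 52074870 with JNJ. Changes are log2(JNJ / DMSO) ± SE, and levels are normalised counts (CPM) as mean ± SD over n = 3 libraries. The SE was worked back from the test, as the absolute log2 change divided by the square root of edgeR's F statistic. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The gene lists, tests and rules for naming genes were fixed before the data were examined, apart from those described as added after the data were seen.

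The 20 most abundant genes took 8.14% to 8.63% of the counts in OCI-Ly1 with DMSO and 9.18% to 10.3% with JNJ, against 10.3% to 11.4% and 10.9% to 11.5% in SU-DHL-4. The TMM scaling factors of OCI-Ly1 lay between 1.067 and 1.081 with DMSO and between 0.909 and 0.960 with JNJ, and those of SU-DHL-4 between 1.001 and 1.049 and between 0.966 and 0.992. Scaling by library totals in place of TMM therefore shifted every log2 change by −0.21 in OCI-Ly1 and by −0.07 in SU-DHL-4, and changes below are relative to the TMM centre. PRMT5 itself (chromosome 14, 22920529 to 22929376), a subunit of the methylosome, rose with JNJ from 57.2 ± 4.8 to 94.8 ± 5.91 CPM in OCI-Ly1 (0.73 ± 0.07, adjusted p = 3.51e-05). In SU-DHL-4 it rose from 49.5 ± 0.624 to 82.8 ± 7.22 CPM (0.74 ± 0.06, adjusted p = 5.5e-07). An inhibitor of the enzyme need not lower its messenger RNA, so these values do not check the labels.

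**Figure D1:**
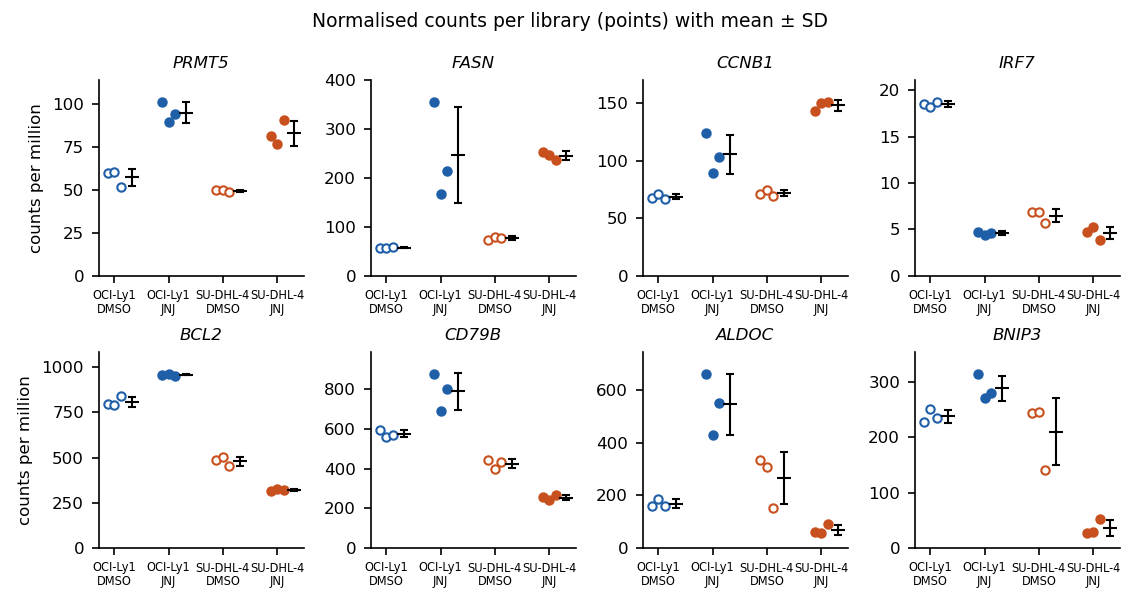
CPM of 8 genes in each of the 12 libraries (open points DMSO, filled points JNJ, linear axes from 0), 3 per group, with the group mean ± SD beside the points. FASN lay between 168 and 356 CPM in the OCI-Ly1 JNJ libraries against 56.4 to 59.7 with DMSO and between 236 and 254 against 73.7 to 80.2 in SU-DHL-4, while BCL2 was at 954 to 963 against 789 to 839 in OCI-Ly1 (log2 change 0.25, and 0.04 with library totals) and at 315 to 325 against 453 to 501 in SU-DHL-4.

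In OCI-Ly1, 72 h of JNJ raised the enzymes of cholesterol and fatty acid synthesis and lowered interferon response genes. Of the 29 measured genes of the former list 28 rose, none fell and 1 did not pass the test (28 rose adjusted over the list alone; median log2 change 1.22). FADS2, a fatty acid desaturase (chromosome 11, 61816203 to 61867354), went from 117 ± 3.77 to 588 ± 138 CPM (2.33 ± 0.15, adjusted p = 5.71e-06). HMGCS1, an early enzyme of the mevalonate pathway, went from 82.9 to 375 CPM (2.18 ± 0.15). FASN, the fatty acid synthase (chromosome 17, 82078338 to 82098236), went from 57.6 ± 1.8 to 246 ± 98.2 CPM (2.10 ± 0.25, adjusted p = 0.000236). Of 33 genes of the type I interferon response, 2 rose, 27 fell and 4 did not pass, the same as adjusted over the list alone (median −0.85). IRF7, a transcription factor that amplifies interferon production (chromosome 11, 612555 to 615950), fell from 18.5 ± 0.313 to 4.58 ± 0.215 CPM (−2.01 ± 0.08, adjusted p = 1.49e-06). The low IFI44L (3.87 to 0.37 CPM, −3.38 ± 0.19) also fell. Both lists passed camera with a preset correlation (adjusted p = 6.8e-12 and 1.4e-06), and neither did with an estimated correlation (adjusted p = 0.727 and 0.401).

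Among abundant single genes of OCI-Ly1 whose DMSO and JNJ libraries did not overlap, large rises included those of NFKBID, a nuclear regulator of NF-kB (4.61 to 23.6 CPM, 2.36 ± 0.19) and FADS2. LIPG, the endothelial lipase, rose from 13.7 to 65.4 CPM (2.26 ± 0.16) and SLCO4A1, an organic anion transporter, by 2.23 ± 0.25. Deep falls included those of SPNS3 (29.1 to 2.63 CPM, −3.46 ± 0.36, adjusted p = 0.000118) and DPY19L2 (12.6 to 1.74 CPM, −2.85 ± 0.16). ARG2, the mitochondrial arginase, fell from 70.1 to 11.1 CPM (−2.66 ± 0.27). UTP14C had 0 counts in every DMSO library and 906, 293 and 426 with JNJ, at least 112-fold higher over a floor of 3 counts per library. Its value and this bound are uncertain because it shares its place in the genome with ALG11, which fell in the same libraries (−0.79). In all, edgeR called 4095 genes higher and 4260 lower among 12664 tested (66.0%), of which 472 and 845 changed by a log2 value of at least 1. In 72.4% of the tested genes the 3 DMSO and 3 JNJ libraries did not overlap, where chance gives 10%. Higher genes were 49.0% of the calls, 27.4% with library totals (2400 higher, 6348 lower) and 61.8% with limma on TPM (5380 higher, 3328 lower). Values of small changes below moved by over 1.5 times with library totals because of the shift of −0.21. On log2(TPM + 1), which understates changes of low genes, IFI44L stood at −1.09.

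Several lists of growth and B-cell genes also stood above the other genes of OCI-Ly1. Of 72 cytoplasmic ribosomal proteins 64 rose, none fell and 8 did not pass (66 rose adjusted over the list alone; median 0.36, and 0.15 with 43 higher and 3 lower under library totals). RPL14 rose by 1.11 ± 0.06, but single values in this family are uncertain because of its many pseudogenes. Of 32 genes of G2/M and mitosis 25 rose, 1 fell and 6 did not pass, the same adjusted over the list alone (median 0.42, and 0.21 with 19 higher and 6 lower under library totals). The mitotic cyclins CCNB1 (68.3 to 105 CPM, 0.62 ± 0.10) and CCNB2 (0.76 ± 0.09) rose. Of 24 genes of B-cell identity and B-cell receptor signalling 18 rose, 4 fell and 2 did not pass (20 and 4 adjusted over the list alone; median 0.45, and 0.24 with 18 higher and 4 lower under library totals). CD79B, a signalling chain of the B-cell receptor (chromosome 17, 63928740 to 63932331), rose from 575 to 789 CPM (0.46 ± 0.08, adjusted p = 0.00106) and VPREB3 by 0.41 ± 0.06. Of 21 germinal centre genes 16 rose, 2 fell and 3 did not pass, the same adjusted over the list alone (median 0.32, and 0.12 with 8 higher and 3 lower under library totals). GCSAM rose by 1.03 ± 0.06, SERPINA9 by 0.97 ± 0.07 and P2RY8, a receptor of germinal centre B cells, by 0.64 ± 0.07. Camera's adjusted p-values for these lists were 2.5e-12, 2.1e-05, 0.000167 and 0.000877 in that order. With an estimated correlation the adjusted p was 0.727, 0.727, 0.583 and 0.401.

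Metabolic and RNA-processing lists made up the rest of the 11 lists that moved in OCI-Ly1. Of 21 glycolysis genes 18 rose, 2 fell and 1 did not pass (median 0.52, and 0.31 with 14 higher and 3 lower under library totals). The aldolase ALDOC rose from 169 ± 15.7 to 547 ± 117 CPM (1.70 ± 0.14, adjusted p = 1.82e-05) and the muscle-type phosphofructokinase PFKM by 0.82 ± 0.07, while the liver-type PFKL fell (−0.35 ± 0.06). Of 30 nuclear-encoded genes of the respiratory chain 21 rose, 1 fell and 8 did not pass (22 and 1 adjusted over the list alone; median 0.28, and 0.07 with 11 higher and 5 lower under library totals). Of 38 genes of the spliceosome and splicing factors 22 rose, 5 fell and 11 did not pass (median 0.23, and 0.02 with 13 higher and 11 lower under library totals). PRPF3 rose by 1.31 ± 0.05 (adjusted p = 1.49e-06), HNRNPA2B1 by 1.27 ± 0.06 and PRPF8 by 0.80 ± 0.05. Of 13 genes of the PRMT5 complex and its Sm substrates 9 rose, none fell and 4 did not pass (median 0.35, and 0.14 with 6 higher and 3 lower under library totals), among them PRMT5 and the Sm protein SNRPD3 (0.55 ± 0.06). WDR77, the partner of PRMT5 in the methylosome, did not pass (0.03 ± 0.14, adjusted p = 0.883) and fell without OCI-Ly1 JNJ replicate 1 (−0.19). Of 25 ATF4 stress response genes 1 rose, 16 fell and 8 did not pass (median −0.55). PPP1R15A, which directs dephosphorylation of eIF2-alpha, fell from 75.4 to 38.1 CPM (−0.99 ± 0.08). The glycolysis, spliceosome, PRMT5 and ATF4 counts were the same adjusted over the list alone. Camera gave adjusted p = 0.000642, 0.000341, 0.00096, 0.00778 and 0.00326 in the order of the 5 lists. With an estimated correlation it gave adjusted p = 0.798, 0.727, 0.401, 0.727 and 0.835. By fry, which tests a list without comparing it with other genes, 21 lists passed but not the ATF4 list (adjusted p = 0.0668, over a range of 0.000316 to 0.835 across the alternatives). Other splits of the same 6 libraries gave up to 14 lists, so the number of lists alone does not set the real split apart. Those splits mix DMSO and JNJ libraries and still carry part of the JNJ effect, so they do not measure chance.

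Apoptosis genes of OCI-Ly1 moved both ways. Of 5 measured anti-apoptotic BCL2 family genes 3 rose, none fell and 2 did not pass, also adjusted over the list alone (median 0.25, and 0.04 with library totals). BCL2, which holds BAX and BAK1 in check (chromosome 18, 63123346 to 63320090), went from 809 ± 26.7 to 959 ± 4.24 CPM (0.25 ± 0.05, adjusted p = 0.0025), and MCL1 (chromosome 1, 150574558 to 150579610) from 318 to 392 CPM (0.30 ± 0.05). BCL2L1, the gene of BCL-XL (chromosome 20, 31664452 to 31723963), went from 84.1 to 136 CPM (0.70 ± 0.05, adjusted p = 1.09e-05). With library totals BCL2 (0.04) and MCL1 (0.09) no longer passed, and BCL2A1 (−0.08 ± 0.10, adjusted p = 0.51) fell (−0.28). Of 10 pro-apoptotic family genes 1 rose, 6 fell and 3 did not pass, also adjusted over the list alone. PMAIP1, the gene of NOXA, rose (0.50 ± 0.06, and 0.27 with limma on TPM). BAX (−0.40 ± 0.05), BCL2L11, the gene of BIM (−0.31 ± 0.05), and BBC3, the gene of PUMA (−0.31 ± 0.06), fell. BAK1 (−0.18 ± 0.05) fell and lost its call without OCI-Ly1 DMSO replicate 1 or 2 (−0.18 and −0.17). HRK was at −0.02 (adjusted p = 0.854) and at −0.22, past the test, with library totals. Of 16 death receptor pathway genes 5 rose, 7 fell and 4 did not pass (6 and 8 adjusted over the list alone). CASP8, the initiator caspase of death receptors, fell from 75.6 to 40.4 CPM (−0.90 ± 0.07, adjusted p = 1.22e-05). Its decoy CFLAR (−0.54 ± 0.06, and −0.27 with limma on TPM) and the adaptor TRADD (−0.96 ± 0.09) fell. DAXX rose by 0.93 ± 0.08 and the TRAIL receptor TNFRSF10A by 0.27 ± 0.06 (0.07 and not called with library totals). FAS fell (9.62 to 7.95 CPM, −0.28 ± 0.09, adjusted p = 0.0224), a call lost without OCI-Ly1 DMSO replicate 1, 2 or 3 or JNJ replicate 3 (−0.29 to −0.25). The other TRAIL receptor, TNFRSF10B, was at 0.07, short of the test.

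Further along the pathway in OCI-Ly1, of 12 apoptosome and executioner caspase genes 6 rose, 3 fell and 3 did not pass (2 higher and 5 lower under library totals). APAF1, the scaffold of the apoptosome, rose by 0.65 ± 0.05 and DIABLO, which frees caspases from their inhibitors, by 0.28 ± 0.07 (0.07 and not called with library totals). Of 7 inhibitors of apoptosis 3 rose, 2 fell and 2 did not pass (0 higher and 3 lower under library totals). BIRC5, the gene of survivin, rose by 0.23 ± 0.07, a call lost without OCI-Ly1 DMSO replicate 1 or 3 or JNJ replicate 3 (0.22 to 0.23) and with library totals (0.02). CDKN1A, the gene of the cell cycle inhibitor p21 (90 to 151 CPM, 0.75 ± 0.10), the ubiquitin ligase MDM2 (0.54 ± 0.06), and the polymerase POLH (1.09 ± 0.12) rose, and FDXR (−0.86 ± 0.11) and GADD45A (−0.70 ± 0.07) fell. MDM4 rose by 0.36 ± 0.07 (0.15 and not called with library totals). The camera adjusted p of the anti-apoptotic, pro-apoptotic, death receptor, apoptosome and inhibitor lists was 0.132, 0.334, 0.770, 0.448 and 0.825. The death receptor list had a median of −0.10, a mean of 0.06 and a test direction downward.

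The remaining lists did not move in OCI-Ly1 by camera. Of 30 MYC targets 17 rose and 3 fell (adjusted p = 0.0717, and 0.0497 without OCI-Ly1 DMSO replicate 2, over a range of 0.00735 to 0.727 across the alternatives), with MYC at 0.37 ± 0.08. Of 35 E2F and G1/S genes 15 rose and 8 fell (adjusted p = 0.171). The helicase subunit MCM7 rose by 0.56 ± 0.06, and MCM4 was at −0.08 (adjusted p = 0.31), past the test at −0.14 without OCI-Ly1 JNJ replicate 1 and at −0.29 with library totals. Of 25 genes of homologous recombination and Fanconi anaemia repair 6 rose and 11 fell (adjusted p = 0.574), with RAD54L at 0.77 ± 0.09 and the kinase CHEK1 at 0.09, short of the test. Members that rose and fell were 3 and 4 of 15 other arginine methyltransferase and methionine cycle genes (adjusted p = 0.79), 5 and 7 of 16 plasma cell genes (0.729), and 5 and 4 of 17 NF-kB targets (0.729), where RELB fell (−0.22 ± 0.06). They were 10 and 4 of 23 antigen presentation genes (0.334), 9 and 8 of 21 unfolded protein response genes (0.838) and 5 and 7 of 20 FOXO targets (0.729). Of the rest they were 5 and 2 of 20 replication-dependent histones (0.495) and 5 and 7 of 18 immediate early genes (0.729). Markers of other cells gave 1 higher and 2 lower of 7 for T and NK cells (0.825). LCK, a kinase that B lymphoma lines can also express, rose from 189 to 287 CPM (0.60 ± 0.05). For monocytes and macrophages they gave 4 higher and none lower of 5 (0.171), with CSF1R at 0.0345 to 0.291 CPM. For epithelium and fibroblasts they gave 1 higher and 2 lower of 6 (0.729), with DCN at 9.04 to 3.87 CPM (−1.22 ± 0.11, and −0.55 on log2(TPM + 1)). With library totals the monocyte list passed (adjusted p = 0.0472, over a range of 0.00679 to 0.727 across the alternatives). The medians of the methyltransferase, apoptosome, inhibitor of apoptosis, E2F, MYC, NF-kB, antigen presentation and histone lists changed from positive to negative with the same scaling. Members higher and lower were then 9 and 13 of the MYC targets, 10 and 14 of the E2F genes and 6 and 9 of the antigen presentation genes. They were 3 and 8 of the NF-kB targets and 5 and 12 of the unfolded protein response genes.

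**Figure D2:**
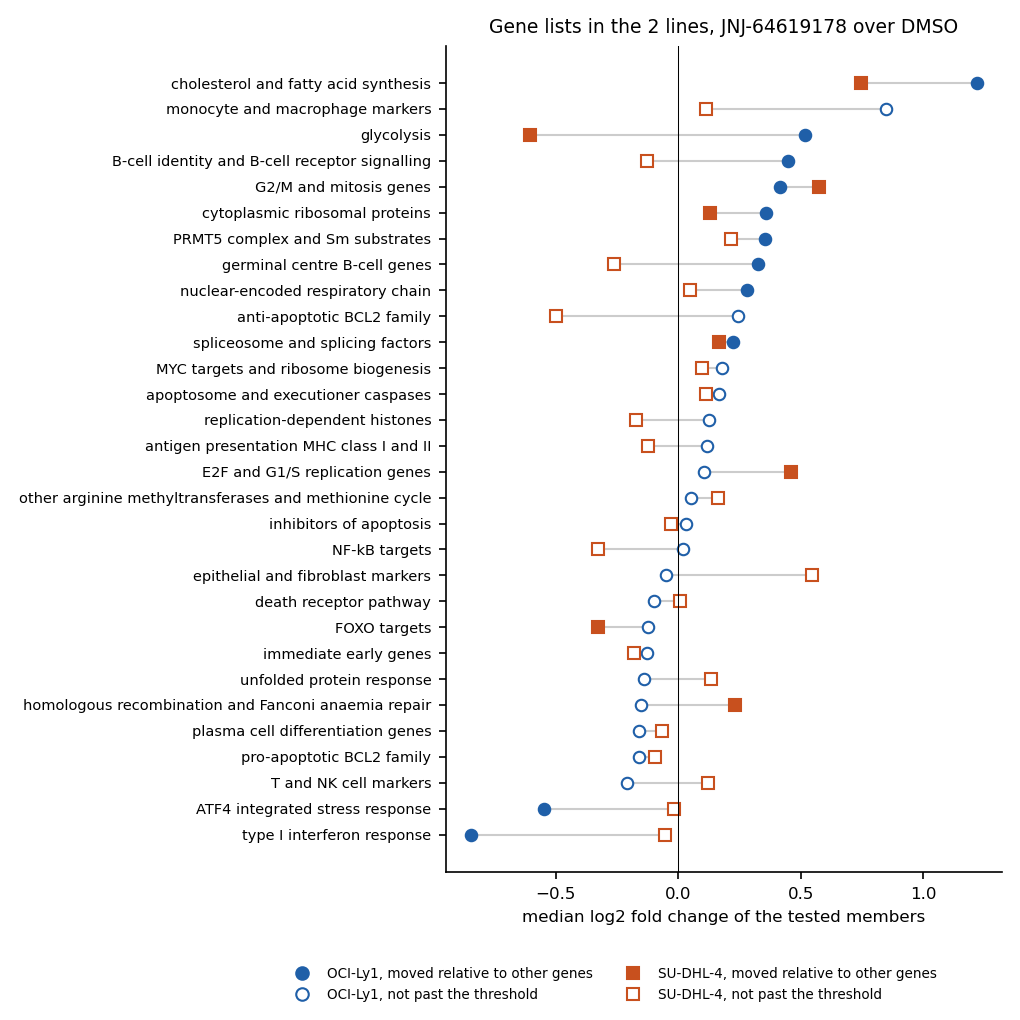
Median log2(JNJ / DMSO) of the tested members of each of 30 gene lists in OCI-Ly1 (circles) and SU-DHL-4 (squares), filled for lists past camera's adjusted p of 0.05 with a preset correlation and open for others. Cholesterol and fatty acid synthesis lay at 1.22 and 0.75, glycolysis at 0.52 and −0.60 and the type I interferon response at −0.85 and −0.05 in OCI-Ly1 and SU-DHL-4. None passed with an estimated correlation, and with library totals 8 medians of OCI-Ly1 and 2 of SU-DHL-4 changed from positive to negative.

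In SU-DHL-4, genes of mitosis, DNA replication and lipid synthesis were higher with JNJ than with DMSO, and glycolysis genes were lower. Of 32 genes of G2/M and mitosis 31 rose, none fell and 1 did not pass (median 0.57). CCNB1 rose from 71.7 to 148 CPM (1.04 ± 0.05, adjusted p = 1.24e-08) and CCNB2 by 1.10 ± 0.06. Of 35 E2F and G1/S genes 25 rose, 4 fell and 6 did not pass (median 0.46), with the replicative helicase subunits MCM7 (1.13 ± 0.06) and MCM4 (1.08 ± 0.06). Of 29 cholesterol and fatty acid synthesis genes 25 rose, 2 fell and 2 did not pass (median 0.75). FASN rose from 77.2 ± 3.31 to 246 ± 9.16 CPM (1.67 ± 0.05, adjusted p = 1.29e-09). FDFT1 rose by 1.35 ± 0.10 and FADS2 from 119 to 249 CPM (1.06 ± 0.08). Of 21 glycolysis genes 3 rose, 13 fell and 5 did not pass (median −0.60). PFKL fell (−1.0 ± 0.06) and PFKM rose (0.31 ± 0.06). ALDOC fell from 265 ± 99.1 to 68.8 ± 18.1 CPM (−1.95 ± 0.40, adjusted p = 0.0131), a call lost without SU-DHL-4 JNJ replicate 1 or 2 (−1.85 and −1.83). All of these counts were the same adjusted over the list alone. Camera's adjusted p was 9.5e-13, 4.3e-05, 4.8e-07 and 0.00947 in that order. With an estimated correlation the adjusted p was 0.788, 0.788, 0.788 and 0.801.

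Large rises among abundant single genes of SU-DHL-4 included those of CAMKV (1.2 to 12.4 CPM, 3.37 ± 0.11, adjusted p = 1.29e-09), the proteasome subunit PSMB6 (16.9 to 72.9 CPM, 2.10 ± 0.07) and STRIP2 (1.80 ± 0.11). WDR4, a subunit of a tRNA methyltransferase, rose from 6.45 to 21.8 CPM (1.76 ± 0.08). EPHB4, an ephrin receptor (3.44 to 11.2 CPM, 1.70 ± 0.15), and NFKBID (8.44 to 26.8 CPM, 1.67 ± 0.08) also rose. Deep falls included those of ATP4A (16.3 ± 7.2 to 0.473 ± 0.666 CPM, −5.08 ± 0.91, adjusted p = 0.00807) and BNIP3, a mitophagy receptor (210 ± 59.7 to 36.4 ± 14.1 CPM, −2.53 ± 0.40). PFKFB4, which sets the level of fructose bisphosphate, fell from 87.4 to 16.9 CPM (−2.37 ± 0.41). So did DPCD (16.7 to 3.54 CPM, −2.23 ± 0.17) and PHACTR1 (32.2 to 7.84 CPM, −2.03 ± 0.27). On log2(TPM + 1) ATP4A stood at −2.62 and CAMKV at 2.23. UTP14C went from 0 counts in all DMSO libraries to 593, 743 and 303, at least 109-fold higher, with the same uncertainty as in OCI-Ly1 (ALG11 at −0.61). Without SU-DHL-4 JNJ replicate 1 it was not called, though its log2 change stayed about as large (12.13 against 12.18). In all, edgeR called 3897 genes higher and 3938 lower among 12356 tested (63.4%), of which 325 and 518 changed by a log2 value of at least 1. Libraries of the 2 groups did not overlap in 67.8% of genes, against 10% by chance. Higher genes were 49.7% of the calls, 40.6% with library totals (3104 higher, 4548 lower) and 49.9% with limma on TPM.

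Other lists that moved in SU-DHL-4 held smaller changes. Of 72 ribosomal proteins 21 rose, none fell and 51 did not pass (1 rose adjusted over the list alone; median 0.13, and 0.06 with 9 higher and 1 lower under library totals), with RPL14 at 0.27 ± 0.07. The list's camera adjusted p of 0.016 rose to 0.126 without SU-DHL-4 DMSO replicate 3 and to 0.0729 without JNJ replicate 2, over a range of 1.44e-06 to 0.927 across the alternatives. Of 25 homologous recombination and Fanconi anaemia genes 14 rose, none fell and 11 did not pass (median 0.23). RAD54L rose by 1.17 ± 0.06 and CHEK1 by 0.79 ± 0.05. Of 38 spliceosome genes 19 rose, 7 fell and 12 did not pass (median 0.17, and 0.09 with 17 higher and 8 lower under library totals). PRPF8 rose by 1.24 ± 0.06 (adjusted p = 6.87e-09), PRPF3 by 1.19 ± 0.06 and HNRNPA2B1 by 0.94 ± 0.06. Camera's adjusted p of 0.0173 and 0.0313 rose without SU-DHL-4 JNJ replicate 3 to 0.0542 (range 0.00789 to 0.801) and 0.0501 (range 0.00216 to 0.788). Of 18 FOXO targets 3 rose, 11 fell and 4 did not pass (median −0.33, adjusted p = 0.0433). TXNIP, a brake on glucose uptake, fell from 181 to 67.3 CPM (−1.43 ± 0.16) and so did GABARAPL1, a gene of autophagy (−1.11 ± 0.09). Counts of the repair, spliceosome and FOXO lists were the same adjusted over the list alone. With an estimated correlation the adjusted p of the ribosomal, repair, spliceosome and FOXO lists was 0.927, 0.801, 0.788 and 0.788. Other splits of the 6 libraries, which mix DMSO and JNJ libraries and do not measure chance, gave up to 15 lists, against the 8 that moved with JNJ. Fry called 16 lists but neither glycolysis (adjusted p = 0.0702, range 3.2e-05 to 0.801) nor the ribosomal list (0.3).

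Of the 5 anti-apoptotic BCL2 family genes in SU-DHL-4, none rose, 4 fell and 1 did not pass, also adjusted over the list alone (median −0.50). BCL2 went from 480 ± 24.6 to 321 ± 5.67 CPM (−0.58 ± 0.05, adjusted p = 1.24e-06) and MCL1 from 518 to 367 CPM (−0.50 ± 0.05, adjusted p = 2.58e-06). BCL2L1 went from 94.3 to 81.9 CPM (−0.20 ± 0.05, adjusted p = 0.00309) and the low BCL2A1 from 2.04 to 1.08 CPM (−0.92 ± 0.17). The list missed camera's threshold (adjusted p = 0.0537) and passed it without SU-DHL-4 DMSO replicate 1 (0.0397) or 3 (0.0459), over a range of 0.00127 to 0.788 across the alternatives. Of 10 pro-apoptotic genes 2 rose, 5 fell and 3 did not pass. PMAIP1 rose (0.55 ± 0.12), and BCL2L11 (−0.32 ± 0.05, and −0.10 and not called with limma on TPM) and HRK (−0.46 ± 0.05) fell. BAX (−0.17 ± 0.06, adjusted p = 0.0302) fell and lost its call without SU-DHL-4 DMSO replicate 1 or 3 or any 1 of the 3 JNJ libraries (−0.18 to −0.14). BBC3 (0.13 ± 0.09, adjusted p = 0.244) passed without SU-DHL-4 JNJ replicate 3 (0.22), and BAK1 was at −0.02, short of the test. Of 16 death receptor genes 5 rose, 6 fell and 5 did not pass. TNFRSF10A (−0.33 ± 0.06), CFLAR (−0.48 ± 0.05, and −0.23 with limma on TPM) and TRADD (−0.83 ± 0.09) fell. DAXX (0.57 ± 0.05) and TNFRSF10B (0.18 ± 0.05, and 0.11 and not called with library totals) rose. CASP8 (−0.17 ± 0.08, adjusted p = 0.068) passed without SU-DHL-4 DMSO replicate 3 (−0.22) or JNJ replicate 3 (−0.27) and with library totals (−0.25). FAS was at 0.26 ± 0.13, short of the test.

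Of 11 apoptosome and executioner caspase genes in SU-DHL-4 5 rose, 2 fell and 4 did not pass, DIABLO rising by 0.91 ± 0.06 and APAF1 by 0.33 ± 0.06. Of 7 inhibitors of apoptosis none rose, 1 fell and 6 did not pass, with BIRC5 at −0.07 (−0.14 and past the test with library totals). CDKN1A (7.81 to 11.5 CPM, 0.57 ± 0.12), MDM2 (0.36 ± 0.06) and POLH (1.07 ± 0.05) rose and FDXR (−0.91 ± 0.07) and GADD45A (−0.67 ± 0.05) fell. MDM4 fell (−0.14 ± 0.05, adjusted p = 0.0224), a call lost without SU-DHL-4 JNJ replicate 2 (−0.14). The adjusted p of the pro-apoptotic, death receptor, apoptosome and inhibitor lists was 0.484, 0.938, 0.269 and 0.707. The death receptor list had a median of 0.00 (−0.07 with library totals) and a test direction downward.

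Lists close to the threshold in SU-DHL-4 depended on single libraries. Of 21 germinal centre genes 2 rose, 12 fell and 7 did not pass (median −0.26, adjusted p = 0.0537), with SERPINA9 at −0.59 ± 0.07, P2RY8 at −0.44 ± 0.05 and GCSAM at −0.01, short of the test. The list passed without SU-DHL-4 DMSO replicate 1 (0.0469) or 3 (0.0294) or JNJ replicate 3 (0.0321) and with library totals (0.0423), over a range of 0.0279 to 0.801 across the alternatives. Of 25 B-cell identity genes 5 rose, 12 fell and 8 did not pass (median −0.13, adjusted p = 0.0793, and 0.0458 without SU-DHL-4 DMSO replicate 3, range 0.00475 to 0.793). CD79B fell from 425 to 253 CPM (−0.75 ± 0.06, adjusted p = 2.73e-07) and so did VPREB3 (−0.78 ± 0.05). Of 20 NF-kB targets 2 rose, 10 fell and 8 did not pass (median −0.33, adjusted p = 0.0637, and 0.0497 without SU-DHL-4 JNJ replicate 1, range 0.00216 to 0.788), with RELB at −0.71 ± 0.09. Of 13 PRMT5 complex and Sm genes 8 rose, 1 fell and 4 did not pass (median 0.22, adjusted p = 0.0612). WDR77 rose from 19.4 to 38.9 CPM (1.00 ± 0.08) and SNRPD3 by 0.53 ± 0.05. The list passed without SU-DHL-4 DMSO replicate 1 (0.0397) or 3 (0.0459) or JNJ replicate 1 (0.0497), over a range of 0.00475 to 0.793.

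Of 30 MYC targets in SU-DHL-4 10 rose and 5 fell (8 and 5 adjusted over the list alone, adjusted p = 0.454). MYC was at −0.11 ± 0.15 (adjusted p = 0.526) and past the test without SU-DHL-4 JNJ replicate 3 (−0.31). Members that rose and fell were 8 and 3 of 15 other arginine methyltransferase genes (adjusted p = 0.269), 5 and 7 of 18 plasma cell genes (0.499), 5 and 11 of 24 antigen presentation genes (0.212) and 4 and 6 of 20 interferon response genes (0.818). Among the last, IRF7 fell (−0.49 ± 0.12). Further counts were 8 and 6 of 25 ATF4 genes (0.938), 7 and 4 of 21 unfolded protein response genes (0.667; 7 and 3 adjusted over the list alone), 1 and 1 of 8 histones (0.818) and 1 and 8 of 18 immediate early genes (0.269). With library totals the balance turned to 5 higher and 8 lower MYC targets, 6 and 8 ATF4 genes and 5 and 6 unfolded protein response genes. Of 30 respiratory chain genes 11 rose and 5 fell (0.402), with a median of 0.05 that became −0.02 with library totals. Markers of other cells gave 2 higher and 2 lower of 8 for T and NK cells (0.872), with LCK at 103 to 135 CPM (0.39 ± 0.09). They gave 2 and 2 of 5 for monocytes and macrophages (0.938), with a median of 0.11, a mean of −0.07 and CSF1R at 0.372 to 1.19 CPM, and 2 and 1 of 5 for epithelium and fibroblasts (0.938), with DCN at 32.1 to 14.9 CPM (−1.11 ± 0.07). The mitochondrially encoded list had no gene in either table and was not tested.

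**Figure D3:**
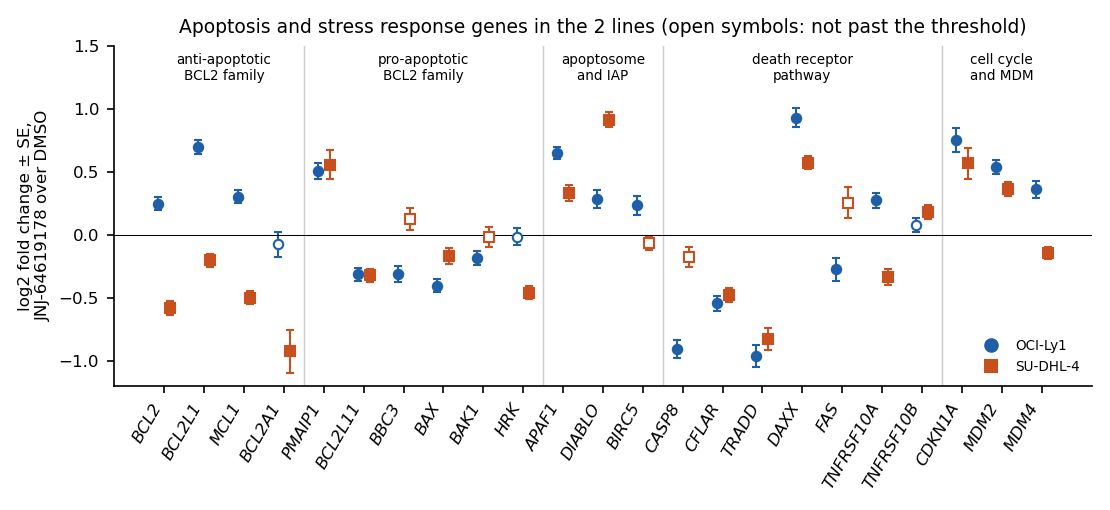
Log2(JNJ / DMSO) of apoptosis and stress response genes in OCI-Ly1 and SU-DHL-4 (3 libraries per group), with error bars of 1 SE and filled points for an adjusted p of at most 0.05. BCL2 lay at 0.25 and −0.58, MCL1 at 0.30 and −0.50 and BCL2L1 at 0.70 and −0.20, and with library totals the OCI-Ly1 values of BCL2 (0.04) and MCL1 (0.09) no longer passed the test.

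Many genes moved the same way in both lines, with the lipid synthesis genes FADS2, HMGCS1, FASN and FDFT1, the splicing factors PRPF3, PRPF8 and HNRNPA2B1, and POLH higher in both. HDHD2 (chromosome 18, 47107410 to 47150500) fell from 45.3 to 12.9 CPM in OCI-Ly1 (−1.81 ± 0.06, adjusted p = 1.49e-06). In SU-DHL-4 it fell from 81.3 to 24 CPM (−1.76 ± 0.06, adjusted p = 1.64e-09). Other genes lower in both were ENKD1 (−1.81 ± 0.08 and −1.59 ± 0.11), TXNIP (978 to 257 CPM, −1.93 ± 0.13, and −1.43 ± 0.16) and COA5, a factor of cytochrome c oxidase assembly (−1.38 and −1.26). The read-through gene ANKHD1-EIF4EBP3 fell in both (−2.03 ± 0.08 and −1.60 ± 0.09), a value that is uncertain because it overlaps ANKHD1, which rose in both (0.76 and 0.93). WDR4 rose in both (1.27 in OCI-Ly1) and FDFT1 of OCI-Ly1 stood at 1.85 ± 0.17. Of 11844 genes tested in both lines 2160 were higher in both, where independent lists would share 1265 (odds ratio 4.63, one-sided Fisher's exact test, p = 1.3391e-298). A further 2122 were lower in both, where independent lists would share 1249.5 (odds ratio 4.47, one-sided Fisher's exact test, p = 3.2446e-285). Fisher's test takes genes as independent units, which they are not, so both of its p-values overstate the evidence. Genes moving in opposite directions numbered 1034, so that 80.5% of the 5316 genes called in both lines moved the same way. Pearson's r of the log2 changes was 0.50 across genes, which are not independent replicates, and lay between 0.368 and 0.526 when each line was represented by 1 DMSO and 1 JNJ library (81 combinations, SD 0.040). With library totals 1220 genes were higher and 3154 lower in both.

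**Figure D4:**
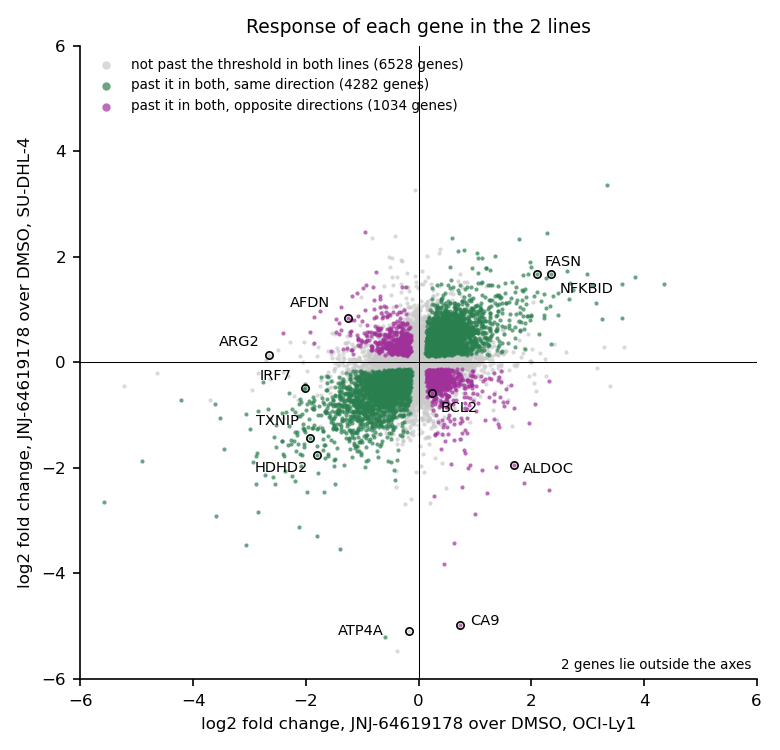
Log2(JNJ / DMSO) of each gene tested in both lines, OCI-Ly1 on the horizontal and SU-DHL-4 on the vertical axis, each gene a point. Genes called in both lines the same way numbered 4282 and genes called in opposite directions 1034, the other 6528 were not called in both, and 2 genes lie outside the axes at ±6.

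The lines differed in B-cell, BCL2 family, glycolysis and interferon genes. A test of the difference itself (SU-DHL-4 minus OCI-Ly1) gave −0.67 as the median of 25 B-cell identity genes (0 more positive and 20 more negative in SU-DHL-4), with CD79B at −1.18 ± 0.11 and VPREB3 at −1.17. The median of 21 germinal centre genes was −0.49 (1 and 14), with SERPINA9 at −1.54, P2RY8 at −1.06 and GCSAM at −1.01. That of the 5 anti-apoptotic genes was −0.80 (0 and 4), with BCL2L1 at −0.88, BCL2 at −0.80 ± 0.08 (adjusted p = 8.78e-07), MCL1 at −0.78 and BCL2A1 at −0.82. The 21 glycolysis genes had a median difference of −0.93 (0 and 19), with ALDOC at −3.62, PFKL at −0.63 and PFKM at −0.48. Interferon response genes differed by 0.70 in the median of 32 (16 and 2), of which 12 were too low in SU-DHL-4 to be tested there, and by 0.75 in the 20 tested in both lines (14 and 1), with IRF7 at 1.54. ATF4 genes differed by 0.56 in the median of 26 (14 and 3). Medians of the cell cycle lists were 0.25 for 35 E2F genes (20 and 3), with MCM4 at 1.19 and MCM7 at 0.59, and 0.27 for 32 mitosis genes (18 and 0), with CCNB1 at 0.45 and CCNB2 at 0.36. The 25 repair genes differed by 0.32 (17 and 0), with CHEK1 at 0.73 and RAD54L at 0.42. The 29 lipid synthesis genes differed by −0.54 (0 and 20), with FADS2 at −1.24 and HMGCS1 at −1.0. Further medians were −0.23 for 72 ribosomal proteins (0 and 24, RPL14 −0.82), −0.22 for 30 respiratory chain genes (4 and 15), −0.36 for 20 NF-kB targets (1 and 7, RELB −0.47) and −0.19 for 24 antigen presentation genes (4 and 11). Adjusted over the list alone the counts were the same except 18 and 2 (interferon), 17 and 3 (ATF4), 5 and 15 (respiratory chain) and 0 and 20 (ribosomal). Camera called these 14 lists, with adjusted p-values from 1.1e-09 (B-cell identity) to 0.0249 (antigen presentation), in a test added after the data were seen. With an estimated correlation none passed, the lowest adjusted p being 0.165 (B-cell identity and anti-apoptotic BCL2 family). A list of genes raised by low oxygen, drawn up after the data were seen and without members of the glycolysis list, differed in the same direction as glycolysis (median −1.24).

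Single genes with wide differences included CA9, a carbonic anhydrase (chromosome 9, 35673928 to 35681159), with −5.67 ± 0.78 (adjusted p = 0.000286). It rose from 99.6 to 165 CPM in OCI-Ly1 (0.73 ± 0.11) and fell from 2.13 to 0.0651 CPM in SU-DHL-4 (−4.97 ± 0.68, and −1.57 on log2(TPM + 1)), where the JNJ libraries held 1, 2 and 7 counts. ATP4A differed by −4.90. In OCI-Ly1 it was at −0.17, short of the test, and past it at −0.35 without OCI-Ly1 JNJ replicate 2. IGFBP2, an insulin-like growth factor binding protein, differed by −4.26 and fell in SU-DHL-4 from 2.74 to 0.19 CPM (−3.83 ± 0.40, and −2.06 on log2(TPM + 1)). PHACTR1 (1.13 in OCI-Ly1, difference −3.14), PFKFB4 (0.77 ± 0.14, difference −3.12) and BNIP3 (0.28 ± 0.07, difference −2.78) rose in OCI-Ly1 and fell in SU-DHL-4, BNIP3 not called in OCI-Ly1 with library totals (0.07) or in one fit of all 12 libraries (0.26). Positive differences included that of ARG2 (2.82 ± 0.33, adjusted p = 9.22e-05). ARG2 was at 24.5 to 27.1 CPM in SU-DHL-4 (0.15), short of the test and past it at 0.20 without SU-DHL-4 DMSO replicate 1. SDC3 differed by 2.23 and fell in OCI-Ly1 from 14 to 3.81 CPM (−1.87 ± 0.18, and −1.15 on log2(TPM + 1)). AFDN, the gene of afadin (chromosome 6, 167826564 to 167972023), fell in OCI-Ly1 (55.7 to 23.3 CPM, −1.26 ± 0.08) and rose in SU-DHL-4 (19.1 to 34.5 CPM, 0.85 ± 0.07). Its difference was 2.13 ± 0.11 (adjusted p = 1.53e-08). WDR77 differed by 1.00 (adjusted p = 0.000603), and the OCI-Ly1 value it rests on fell to −0.19 without OCI-Ly1 JNJ replicate 1. EPHB4 differed by 1.93, at −0.21 in OCI-Ly1, short of the test and past it at −0.39 without OCI-Ly1 JNJ replicate 1. In all 5971 of 13062 tested genes differed (45.7%), 3237 with a more positive and 2734 with a more negative change in SU-DHL-4, 973 of them by a log2 value of at least 1.

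Among apoptosis genes the difference reached CASP8 (0.75), DIABLO (0.65), TNFRSF10A (−0.59), FAS (0.55), MDM4 (−0.48), BBC3 (0.46), HRK (−0.42) and DAXX (−0.34, and −0.22 with library totals). APAF1 (−0.29) was not called with library totals (−0.18). BAX (0.25) lost its call without OCI-Ly1 DMSO replicate 1 or 2 or SU-DHL-4 DMSO replicate 2 (0.17 to 0.25), and BIRC5 (−0.28) without OCI-Ly1 DMSO replicate 1, SU-DHL-4 DMSO replicate 1 or SU-DHL-4 JNJ replicate 3 (−0.26 to −0.24) and with library totals (−0.16). MYC (−0.46, adjusted p = 0.0444) lost its call without any 1 of the 12 libraries except OCI-Ly1 JNJ replicate 2 and SU-DHL-4 JNJ replicate 3 (−0.50 to −0.37), and also with no low-count filter (−0.46) and with library totals (−0.34). PRMT5 did not differ past the test (0.04).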

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

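The list tests of the difference, the effective length tests, library totals, TPM with limma, and the tests of the BCL2 family, glycolysis and length patterns were chosen after results were seen; the gene tests of the difference were planned.

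The response to JNJ differed between the lines in 5971 genes and in 14 gene lists, by the test of the difference itself (SU-DHL-4 minus OCI-Ly1, log2). The 14 lists passed camera with a preset correlation, and none passed with an estimated correlation (lowest adjusted p = 0.165). Median differences of the lists were −0.80 for the anti-apoptotic BCL2 family, 0.25 for E2F and G1/S genes, 0.27 for mitosis genes, 0.32 for homologous recombination genes, −0.49 for germinal centre genes, −0.67 for B-cell identity, −0.36 for NF-kB targets, 0.70 for the interferon response, −0.19 for antigen presentation, −0.54 for lipid synthesis, 0.56 for the ATF4 response, −0.93 for glycolysis, −0.22 for the respiratory chain and −0.23 for ribosomal proteins. The number of genes was 5971 in the real grouping and at most 4175 in the other 99 of 100 splits within lines, with 906 to 4175 in the 18 splits that kept the real grouping in 1 line and 0 by edgeR in the 81 that kept it in neither. A split that mixes DMSO and JNJ libraries turns the JNJ effect into spread within groups, so these splits do not test an equal response of the lines, and chance stays open in them.

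Single genes whose response was more negative in SU-DHL-4 were CA9 (−5.67), ATP4A (−4.90), IGFBP2 (−4.26), ALDOC (−3.62), PHACTR1 (−3.14), PFKFB4 (−3.12), BNIP3 (−2.78), LIPG (−2.50), DPCD (−1.78), SERPINA9 (−1.54), SLCO4A1 (−1.30), FADS2 (−1.24), CD79B (−1.18), VPREB3 (−1.17), P2RY8 (−1.06), GCSAM (−1.01), HMGCS1 (−1.0), GABARAPL1 (−0.93), BCL2L1 (−0.88), BCL2A1 and RPL14 (both −0.82), BCL2 (−0.80), MCL1 (−0.78), NFKBID (−0.66), PFKL (−0.63), TNFRSF10A (−0.59), MDM4 and PFKM (both −0.48), RELB (−0.47), MYC (−0.46), HRK (−0.42), DAXX (−0.34), HNRNPA2B1 (−0.30), APAF1 (−0.29) and BIRC5 (−0.28). More positive were BAX (0.25), CCNB2 (0.36), RAD54L (0.42), CCNB1 and ANKHD1-EIF4EBP3 (both 0.45), PRPF8 and BBC3 (both 0.46), FAS (0.55), MCM7 (0.59), DIABLO (0.65), CHEK1 (0.73), CASP8 (0.75), WDR77 (1.00), MCM4 (1.19), STRIP2 (1.27), PSMB6 (1.43), IRF7 (1.54), SPNS3 (1.83), EPHB4 (1.93), AFDN (2.13), SDC3 (2.23) and ARG2 (2.82). NFKBID was not called without OCI-Ly1 DMSO replicate 1 or 3, SU-DHL-4 DMSO replicate 1 or SU-DHL-4 JNJ replicate 3, and stood at −0.39 without OCI-Ly1 JNJ replicate 1 (range of the 5 values −0.65 to −0.39). By limma-voom it was not called either (−0.62). The calls of BAX, BIRC5 and MYC also ended on leaving out single libraries: BAX without OCI-Ly1 DMSO replicate 1 or 2 or SU-DHL-4 DMSO replicate 2 (0.17 to 0.25), BIRC5 without OCI-Ly1 DMSO replicate 1, SU-DHL-4 DMSO replicate 1 or SU-DHL-4 JNJ replicate 3 (−0.26 to −0.24), and MYC without any of the 12 except OCI-Ly1 JNJ replicate 2 and SU-DHL-4 JNJ replicate 3 (−0.50 to −0.37). MYC was not called with no low-count filter either (−0.46). With library totals HNRNPA2B1 (−0.19), APAF1 (−0.18), BIRC5 (−0.16) and MYC (−0.34) were no longer called.

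Of 5 anti-apoptotic BCL2 family genes 3 rose with JNJ in OCI-Ly1 and 4 fell in SU-DHL-4, although the list did not pass camera in either line and its difference between lines did with a preset correlation only. The difference held under the scaling that brought it nearest to 0 (median −0.69), so the choice among TMM, RLE and library totals does not make it. Library totals moved log2 changes by only −0.21 in OCI-Ly1 and −0.07 in SU-DHL-4, so a larger scaling error was not tested. The difference also held on TPM, which divide by transcript length (−0.84), and this argues against a length change inside the counts. The rise in OCI-Ly1 alone stays open, since its median was 0.038 with library totals and no value says which scaling is right. A candidate explanation for the difference is a line-specific response to PRMT5 inhibition, a hypothesis that came from these same libraries and was not itself tested.

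Of 21 glycolysis genes 18 rose with JNJ in OCI-Ly1 and 13 fell in SU-DHL-4, with both lists past camera with a preset correlation, neither past it with an estimated correlation, and the SU-DHL-4 list short of fry's threshold. The smallest median change in the direction of each line was 0.31 under RLE or library totals and 0.42 with any 1 library left out. The choice among TMM, RLE and library totals therefore does not make the pattern, and the second value argues against a single library as its cause. A scaling error larger than the gap between these scalings was not tested. Oxygen or cell density in the cultures may be the cause and stays open, because genes raised by low oxygen that are not in the glycolysis list differed in the same way (median −1.24) and the labels say nothing of density. The low-oxygen genes were chosen after results were seen. They include PFKFB4 and PDK3, of the same families as PFKFB3 and PDK1 of the glycolysis list. CA9, BNIP3 and PFKFB4 among them had already been named for their wide changes. Mean log2 levels of those genes, relative to each line's mean, were 0.67, 0.64 and 0.13 in the SU-DHL-4 DMSO libraries, −0.55, −0.62 and −0.27 with JNJ, −0.37, −0.23 and −0.37 in OCI-Ly1 with DMSO, and 0.53, 0.09 and 0.35 with JNJ. A line-specific effect of JNJ on these genes is untested apart from culture conditions.

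The TPM columns, compared with the counts, give an effective transcript length per gene, which the comparisons above do not use. With JNJ this length changed by at least 0.1 (log2), at an adjusted p under 0.05 by limma, in 458 of 8416 genes of OCI-Ly1 (237 longer, 221 shorter) and in 353 of 8359 of SU-DHL-4 (168 longer, 185 shorter). Changes of any size passed in 2114 and 1587 genes. Among 7754 genes in both, 206 with a change of at least 0.1 were shared where independent lists would share 16.7 (one-sided Fisher's exact test, p = 2.0905e-204). Genes are not independent and may differ in how readily this length shifts, so the 16.7 and the p-value do not measure a shared effect of JNJ. The direction was the same in 205 of the 206, which does not rest on that number. Examples were PCID2 (0.44 in both lines), MTA3 (−0.43 in both), PDK3 (−0.45 and −0.44) and ERCC8 (−0.74 and −0.57). Pearson's r of the length changes across genes was 0.713 with no trend removed, 0.71438 with the length trend removed and 0.71366 with the GC trend also removed. Removing these trends moved the shared genes (206, and 205 with a GC value) by at most 0.037 and 0.000565 against median changes of 0.19 in OCI-Ly1 and 0.18 in SU-DHL-4. That is too little to make shifts of 0.1, which argues against library-wide length or GC trends as the cause. Among genes whose length shifted, the shift followed the direction of the gene's expression change little (r of at most 0.13 in size). Sizes regardless of direction were not compared, so a link to expression level stays open. A shift in the mix of transcript isoforms with PRMT5 inhibition is a candidate explanation, as a hypothesis that isoform levels from the reads, not analysed here, would decide, and the unnamed quantifier's model of length stays open.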

How the results depend on the processing

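Scaling by library totals and limma on log2(TPM + 1) were chosen after the data were seen, and the other alternatives were fixed before. Each count of genes, the correlation and each count of lists stayed within 1.5 times its value under DESeq2, RLE, no low-count filter, the stricter filter, limma-voom, all 12 libraries in one fit and an adjusted p of 0.01 and limma on TPM, wherever these apply. With a log2 change of at least 1 the counts were 472 higher and 845 lower in OCI-Ly1, 325 and 518 in SU-DHL-4 and 973 for the difference, by the construction of that limit. Library totals gave 2400 higher genes in OCI-Ly1 and 1220 higher in both lines, because that scaling lowers each log2 change of OCI-Ly1 by 0.21. Of the lists, 0 and 0 moved by camera with an estimated correlation (3 and 0 at an unadjusted p under 0.05) and 21 and 16 passed fry, against 11 and 8, and the cause was not tested. Leaving out 1 library gave 3489 to 4264 higher and 3680 to 4449 lower genes in OCI-Ly1, 3460 to 3887 and 3471 to 3989 in SU-DHL-4, 5252 to 6260 for the difference, 1913 to 2215 higher and 1903 to 2194 lower in both, a correlation of 0.466 to 0.513, and 11 to 12 and 7 to 11 lists. The replicate number as a block gave 3848 and 4049 genes in OCI-Ly1, 3949 and 3957 in SU-DHL-4, 5699 for the difference, 2107 and 2065 in both, a correlation of 0.50, and 11 and 8 lists. In SU-DHL-4 it ended the calls of ALDOC, ATP4A, BNIP3 and PFKFB4, whose log2 changes stayed about as large (−1.90, −4.99, −2.54 and −2.32). Libraries with the same number correlated at −0.080, −0.093 and −0.018 in OCI-Ly1 and at 0.095, −0.022 and 0.103 in SU-DHL-4, and not every library correlated best with its own number. Calls of named genes kept or lost numbered 408 and 8 with DESeq2, 410 and 6 with RLE, 412 and 4 with no filter, 396 and 0 with the stricter filter, 413 and 3 with limma-voom, 403 and 13 with the block, 294 and 3 with 12 libraries in one fit, 385 and 31 with library totals, 284 and 14 with TPM, and 3062 and 142 over all left-out libraries. Reversed values were those of WDR77 in OCI-Ly1 without JNJ replicate 1 (−0.19, range −0.19 to 0.14 over left-out libraries) and SDHC in OCI-Ly1 with library totals (−0.045). With TPM in OCI-Ly1, CD8A (0.000539), FCN1 (0.30) and COL1A1 (0.19), 3 genes under 1 CPM, also reversed. The TPM fit centred each library at its median, which moves genes near the floor too, and its part in these reversals was not tested. The cause of the other reversals was not tested either. Alternatives for normalized units (pseudocount, low-value filter) were not run because the tables hold counts. Depth limits genes under about 1 CPM, where few counts fix a log2 change.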

Other observations

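The 13 gene families below, their tests and the matched lists were chosen after results were seen. Tubulin genes rose with JNJ in both lines, 14 up and 3 down of 21 in OCI-Ly1 (median log2 change 0.42, camera adjusted p = 0.0129; 0.21 with 11 up and 5 down under library totals) and 16 up and 3 down of 21 in SU-DHL-4 (0.51, adjusted p = 0.00106). Nucleoporin genes also rose, 13 up and 4 down of 21 (0.25, adjusted p = 0.0414; 0.04 with 5 up and 6 down under library totals) and 14 up and 4 down of 22 (0.29, adjusted p = 0.0139). In SU-DHL-4 kinesins (15 up and 5 down of 28, 0.26, adjusted p = 0.0215), cytosolic tRNA synthetases (10 and 3 of 17, 0.35, adjusted p = 0.0215) and proteasome subunits (22 and 10 of 39, 0.18, adjusted p = 0.024; 0.11 with 18 and 11 under library totals) rose as families, while chemokines and their receptors fell (0 and 9 of 15, −0.76, adjusted p = 0.0199). Chemokine genes of OCI-Ly1 stood at a median of 0.62 (8 up, 2 down of 11, adjusted p = 0.228). No family passed with an estimated correlation in either line (adjusted p of at least 0.203).

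Genes raised by low oxygen, without members of the glycolysis list, rose in OCI-Ly1 (21 up and 1 down of 24, median 0.65, camera adjusted p = 2.7e-05) and fell in SU-DHL-4 (0 and 16 of 24, −0.74, adjusted p = 0.000148). With an estimated correlation the adjusted p was 0.582 and 0.472.

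Zinc finger (ZNF) genes were lower with JNJ in both lines, 89 up and 201 down of 439 in OCI-Ly1 (median −0.19, camera adjusted p = 0.0276, and 0.756 with an estimated correlation; −0.40 with 47 up and 273 down under library totals) and 71 up and 164 down of 418 in SU-DHL-4 (−0.16, adjusted p = 0.0117, and 0.405; −0.23 with 56 up and 191 down under library totals). Their transcripts have a median GC content of 45.5% against 50.4% for the other genes of OCI-Ly1. In OCI-Ly1, 10000 random lists were matched for GC content, length and level. Of these, with the real list counted among them, 3.24% had a median at or below that of the ZNF genes. The matched lists themselves had a median of −0.14, so these properties may be a source of the fall there. In SU-DHL-4 the matched lists had a median of −0.04, the lowest of them was −0.14, and the ZNF genes stood at −0.16. The share, with the real list counted, was 0.010%, the smallest they can give. Genes drawn at random lack the correlation within a family, so the lists may vary too little. The share therefore cannot decide whether these properties are the whole source in that line.

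Within each line the 6 libraries can be split in 10 ways, too few to give a share under 5%. The real split gave 4095 higher and 4260 lower genes in OCI-Ly1 and 3897 and 3938 in SU-DHL-4, and the highest count of the other splits was 0 in both lines by edgeR. Each other split mixes DMSO and JNJ libraries, which turns the JNJ effect into spread within groups, so counts near 0 were built in. Counts of genes or gene lists in the other splits therefore do not measure chance. At an unadjusted p under 0.05 the other splits gave 19 to 46 genes in OCI-Ly1 and 10 to 214 in SU-DHL-4. For gene lists, 4 of the 10 splits gave as many as the real one in OCI-Ly1 (11 lists, highest other 14) and 4 of 10 in SU-DHL-4 (8 lists, highest other 15). Over both lines there are 100 splits. For the genes higher in both (2160, highest other 0) and lower in both (2122, highest other 0) they add nothing to the splits within lines, since no other split of either line called a gene. The correlation of the responses was 0.50 with a highest other of 0.481, and leaving out 1 library took the real value as low as 0.466. The log2 changes of the other splits still carry part of the JNJ effect, so their correlations do not measure chance. The splits therefore cannot decide whether chance made this correlation. For each of these 3 results 1 split was as large, the real one.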
